A study of Homo sapiens with 8 samples.

How the data were processed

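The study profiled MOLM-13 acute myeloid leukemia cells with DIMT1 depletion or with Rosa depletion as a negative control. Per the labels' protocols, cells received cycloheximide at 100 µg/ml for 7 min to hold ribosomes on messenger RNA before lysis. Part of each lysate gave total RNA. Another part was digested with RNase I for 30 min, monosomes were collected from a sucrose gradient, and fragments of 27 to 30 nt were cut from a gel, per the labels' protocols. Ribosomal RNA was depleted from both kinds of sample, and libraries were made with a small RNA kit and sequenced as single 75 bp reads, per the same protocols. Groups and replicate numbers were taken from the sample titles, which give 4 groups of 2 libraries. Nothing in the labels says that replicates came from separate cultures, so p-values of single genes measure the spread between these libraries, which may be technical. P-values of gene lists by camera at a preset correlation rest mainly on the spread across genes, not between libraries. How DIMT1 was depleted and for how long is not given in the sources used here.

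The authors deposited 2 tables of raw counts per gene, 1 for input RNA and 1 for footprints, not normalized, with the column layout of featureCounts per the file headers. The submitters' processing notes name Trimmomatic, Bowtie2, STAR, featureCounts and the build GRCh38, without versions, roles or settings. Annotation release, strand setting and the handling of reads that map to several places are not given in the sources used here. The tables list 20447 genes. Their counted segments appear to be coding sequence. Among 1561 genes with a single segment, 92.2% have a length that is a multiple of 3. Reads in untranslated regions were thus mostly not counted, and lengths are taken as coding lengths. The single-segment genes of other lengths were not examined. Coordinates in the text run from the first to the last counted base on GRCh38, as the files give them. Gene identifiers were matched to symbols in a gene name table, where 20400 matched and 19830 had a symbol. Counted segments of 2009 genes overlap another gene, and where that holds for a named gene it is stated. Genes with near-identical copies (histones, chemokines, HLA, ribosomal proteins with pseudogenes) are uncertain one by one, since reads could have been split, dropped or assigned to a copy.

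Counts were analysed in R 4.3.3 with edgeR 4.0.16. For input RNA and for footprints, the 4 libraries of the assay were fitted alone. Genes were filtered with filterByExpr on group, scaled by TMM factors and tested for DIMT1 against Rosa with the robust quasi-likelihood test. The change in translational efficiency was the interaction between assay and treatment in 1 fit of all 8 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes are DIMT1 over Rosa, with standard errors from the fit. CPM (counts scaled to a common library size) use TMM-scaled library sizes, except for DIMT1 per library, marker sums and totals, which use raw totals. Intervals of single counts and count ratios are exact binomial 95% intervals. They and the floor of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. A group at 0 counts is given a lower bound on the fold against that floor over the group, and a gene with 1 to 3 counts in a group is given a ratio of summed counts with its interval.

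Before the data were examined, 33 gene lists were fixed that fit a leukemia cell line and a factor of ribosome assembly. Of these, 29 had at least 5 measured members in each fit and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation is given beside it, and fry mainly as the number of lists called. In 4 lists fewer than 5 members passed the filter: mitochondrially encoded messenger RNAs, erythroid and megakaryocytic markers, lymphoid markers, and epithelial and stromal markers. Those are given as summed counts. List symbols SOD2, TP53TG1 and DDX58 were not matched. The rule for named genes was also fixed: DIMT1, the 10 largest changes in each direction that passed the test with an average log2 CPM of at least 3 and groups that did not overlap, and the 4 members of smallest p of each list. Where fewer than 3 passed in a direction, the 3 of smallest p were named and said not to pass. The text names some of these list members, and not every gene that the rule selects. NKG7 and the other main contributors to the marker sums were singled out after their values were seen, as was the lack of input counts for UMOD and LAMB2.

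Each test was tried on simulated data with the real means and library sizes, in which 200 genes were changed. For input RNA, edgeR recovered 88% of 4-fold and 58% of 2-fold changes over 9509 genes, with 5.8% false calls. Over 7730 genes in footprints it recovered 63% and 9%, with 4.0% false calls. Over 9471 genes in translational efficiency it recovered 48% and 1%, with no false call. Every recovered gene had the right sign. Camera with the preset correlation called a list moved 1.5-fold in all 3 comparisons and none of 20 unmoved lists. Camera with an estimated correlation gave that moved list adjusted p of 0.243, 0.614 and 0.143. Fry gave it 0.107, 0.231 and 0.0687, so neither called it. Genes were simulated independently of each other, so this could not show how often lists of genes that vary together are called falsely. Nor do these misses show why camera with an estimated correlation called no list in the real data.

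Alternatives were DESeq2 1.42.0, limma-voom, median-ratio factors, library totals only, TMM within each assay, no low-count filter, a filter of at least 50 counts in every library of at least 1 group, nuclear protein-coding genes only, non-robust dispersion, a threshold of 0.1, the replicate number as a block, a fit over all 8 libraries, and leaving out each library. A crossed block and thinning libraries to equal depth were added after the data were seen. Figures were drawn with matplotlib 3.10.9. With 2 libraries per group, no test for outlying libraries and no count over other groupings of the libraries was made.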

Results

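The data comprised 8 libraries from MOLM-13, a human acute myeloid leukemia cell line that carries a KMT2A fusion, in 4 groups of 2. Cells were depleted of DIMT1, the enzyme that dimethylates adenosines near the end of the small ribosomal subunit RNA, or were treated with a Rosa depletion that served as the negative control. From each treatment, input RNA and ribosome footprints were sequenced. Input RNA reports how much of each messenger RNA was present, and footprints, the RNA fragments that ribosomes shield from nuclease, report how many ribosomes sat on it. Libraries were scaled to each other before both were compared, so changes are relative to the other genes. Total counts over coding sequences were 1843484 and 2002501 in the Rosa input libraries and 1062611 and 1039241 in the DIMT1 input libraries. The Rosa footprint libraries held 1722798 and 835325 counts, and the DIMT1 footprint libraries held 202332 in replicate 1 and 728060 in replicate 2. Mean totals were thus lower after DIMT1 depletion in both assays. The log2 CPM of the replicates correlated across genes at 0.976 (Rosa input), 0.978 (DIMT1 input), 0.974 (Rosa footprints) and 0.911 (DIMT1 footprints). Counts within every group differed between replicates by more than sampling noise, as library preparations of the same lysate also would.

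DIMT1 itself (ENSG00000086189, minus strand of chromosome 5, coding segments between 62373018 and 62403772, GRCh38) was measured first, as a check of the labels. Its input RNA was 3.31-fold lower after DIMT1 depletion, with a log2 change of -1.73 ± 0.26 (SE) and an adjusted p of 0.000186 in edgeR's quasi-likelihood test. Raw counts were 140 and 146 in the Rosa input libraries and 27 and 20 in the DIMT1 input libraries, or 74.7 ± 2.27 and 22.5 ± 4.18 CPM (mean ± SD, n = 2). In the footprints, the Rosa libraries held 138 and 44 DIMT1 counts. Footprint replicate 1 of the DIMT1 group held 1 count, or 4.94 CPM with an exact 95% interval of 0.125 to 27.5. The footprint library labelled DIMT1 replicate 2 held 62 counts, or 85.2 CPM (65.3 to 109), a level within the range of the Rosa footprint libraries' intervals. This footprint library therefore goes against its label for the targeted gene. The fitted footprint change was -0.27 ± 0.57 (adjusted p = 0.925). Without the library labelled DIMT1 replicate 2 it was -3.71 (adjusted p = 0.00548), and without replicate 1 it was 0.30 (adjusted p = 0.746). Every direction given below for footprints after DIMT1 depletion includes the library labelled DIMT1 replicate 2.

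**Figure D1:**
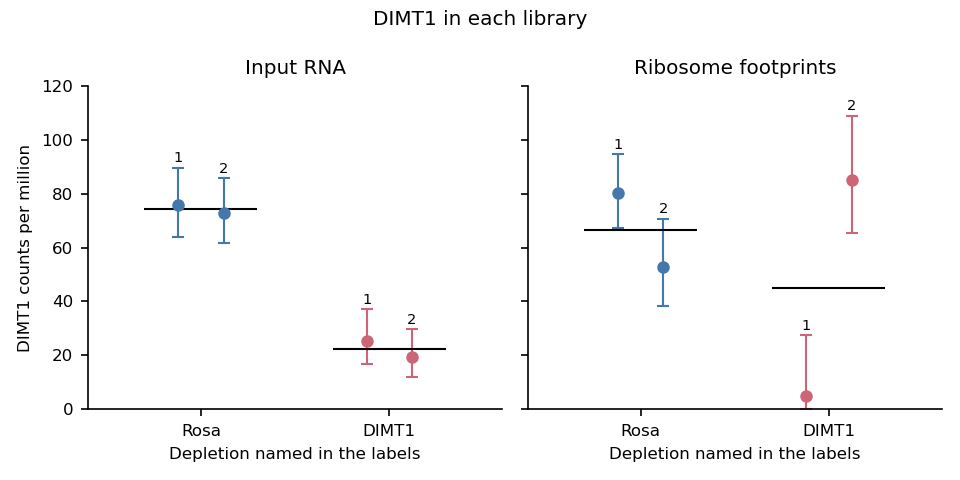
DIMT1 CPM (y axis) in the 4 input RNA libraries and the 4 footprint libraries, by the depletion that the labels name (x axis). Points are libraries with their replicate numbers, bars are exact 95% counting intervals and horizontal lines are group means; the footprint library labelled DIMT1 replicate 2 lies at 85.2, and replicate 1 at 4.94.

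The first comparison asked which messenger RNAs changed in abundance when DIMT1 was depleted. Genes of inflammation were among those that rose most. Complement component C3 (ENSG00000125730, chromosome 19, 6677885 to 6720589) rose 20.9-fold, from 16.4 ± 2.34 to 345 ± 22.5 CPM (mean ± SD, n = 2; adjusted p = 1.22e-11). The neutrophil chemokine CXCL8 (ENSG00000169429, chromosome 4, 73740659 to 73742461) rose 14.5-fold, from 38.2 ± 2.29 to 553 ± 104 CPM. IL1B, which encodes interleukin-1 beta (ENSG00000125538, chromosome 2, 112830364 to 112836229), had 2 counts in the Rosa and 125 in the DIMT1 input libraries, a ratio of 115 with a 95% counting interval of 31.1 to 959. In total, 1060 of 9509 genes changed at an adjusted p under 0.05, 596 higher and 464 lower, and 326 of the former and 93 of the latter changed at least 2-fold. The test with unadjusted p under 0.05 gave 2317 genes against 475 by chance. The count was 200 without DIMT1 input replicate 1, 208 without DIMT1 input replicate 2 and 1699 without Rosa input replicate 1.

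Besides IL1B and C3, the 10 largest increases were those of IL4I1, a secreted amino acid oxidase (80.5-fold), the cytokine IL32 (23.7-fold), the kinase SGK1 (23.3-fold), the adhesion molecule ICAM1 (19.4-fold) and HLA-DRA, the alpha chain of an MHC class II molecule (16.2-fold, uncertain because HLA genes resemble each other). The metalloprotease ADAMDEC1, with 2 Rosa counts, had a count ratio of 83.6 (22.5 to 701). The sugar transporter SLC2A6, with 1 Rosa count, had a ratio of 69.9 (11.8 to 2830). The phospholipase PLA2G4C, with 3 Rosa counts, had a ratio of 33.7 (10.9 to 168). All 10 kept their call when any 1 input library was left out, but folds moved. IL4I1 rose 153-fold and HLA-DRA 10.5-fold without Rosa input replicate 1, and IL4I1 rose 52.4-fold, ICAM1 38.5-fold and HLA-DRA 37.2-fold without Rosa input replicate 2. SGK1 rose 14.4-fold without DIMT1 input replicate 2. IL1B, ADAMDEC1 and SLC2A6 each had their Rosa counts in a single library. The largest decreases were smaller and included those of H2BC18, a histone gene (4.70-fold), SCOC (4.26-fold), ARHGEF39 (4.13-fold), C15orf40 (3.72-fold), POLE2, a subunit of a replicative DNA polymerase (3.31-fold), DIMT1, ZBTB49 (3.13-fold), the histone gene H2BC9 (log2 change -1.59) and the centriole protein SASS6 (2.95-fold). C15orf40 shares 8.4% of its counted length with RAMAC. Among the 10 largest decreases, 8 lost their call without DIMT1 input replicate 1 and 9 without DIMT1 input replicate 2, with no change of sign. Without DIMT1 input replicate 1 the fold was 10.3 for H2BC18 (adjusted p = 0.0162) and 5.12 for POLE2 (adjusted p = 0.0596). Without DIMT1 input replicate 2 it was 3.08 for H2BC18 (adjusted p = 0.0645) and 7.48 for SCOC (adjusted p = 0.108). C15orf40 also lost it without Rosa input replicate 1, as did SCOC and ZBTB49 without Rosa input replicate 2.

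**Figure D2:**
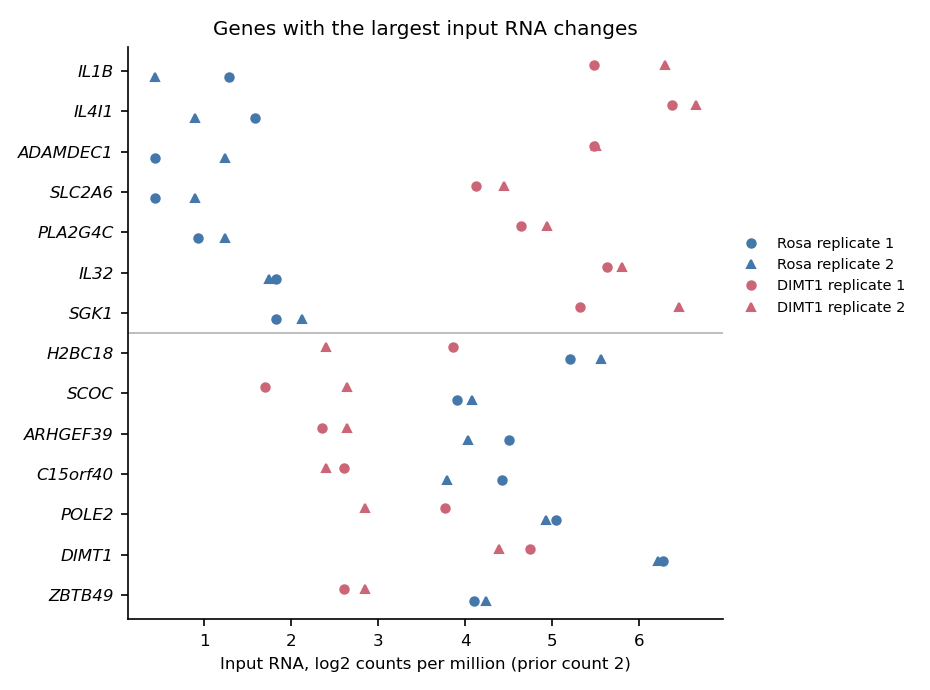
Log2 CPM in input RNA (x axis, prior count of 2) of the 7 genes with the largest increases, above the line, and the 7 with the largest decreases, below it. Each point is a library, colored by treatment and shaped by replicate number, and genes were shown only if the groups did not overlap.

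Among gene lists fixed beforehand, 4 were higher in input RNA by camera, which compares a list with all other genes. The NF-kB and inflammatory response list moved most. Of its 37 genes 23 were measured, and 22 of these rose (23 adjusted over the list alone), with a median log2 change of 2.63 (adjusted p = 9.47e-80, and 0.12 with an estimated correlation). They included CXCL8 and ICAM1 along with the pathway's own inhibitors NFKBIA (9.09-fold) and TNFAIP3 (6.66-fold, from 42.7 ± 5.15 to 284 ± 55.4 CPM, n = 2). In both assays the filter keeps genes expressed in 1 group alone. Members low in Rosa could thus enter through the DIMT1 libraries, which can raise the share that rose and the median. Without the filter, 36 genes of the list summed to 571.7 and 605.2 CPM in the Rosa input libraries. In the DIMT1 input libraries they summed to 2835 and 3385. In the lysosome and autophagy list 17 of 30 members rose (20 adjusted over the list alone; median 0.70, adjusted p = 7.85e-16; adjusted p = 0.12 with an estimated correlation). PSAP, the precursor of the lysosomal saposins, rose 4.59-fold, the autophagy receptor SQSTM1 3.95-fold and the protease CTSH 5.57-fold. Of the 31 myeloid differentiation markers 12 rose (13 adjusted over the list alone; median 0.63, adjusted p = 4.68e-11; adjusted p = 0.162 with an estimated correlation). The median was 0.34 without Rosa input replicate 1 and 0.98 without Rosa input replicate 2. CYBB, the catalytic subunit of the phagocyte oxidase, rose 7.16-fold, the integrins ITGAX and ITGAM 5.32-fold and 4.03-fold, and lysozyme, LYZ, 2.43-fold to 2206 ± 215 CPM (n = 2). Of the 33 p53 target genes 10 rose (14 adjusted over the list alone; median 0.64, adjusted p = 1.86e-10; adjusted p = 0.12 with an estimated correlation). These included MDM2, the ubiquitin ligase that degrades p53 (2.43-fold), the death receptor TNFRSF10B (2.21-fold), ZMAT3 (2.99-fold) and FUCA1 (3.84-fold). No member of these 4 lists fell. Alongside these groups, the 20 lymphoid marker genes summed to 90 and 103.4 CPM in the Rosa input libraries and 184.5 and 182.8 in the DIMT1 input libraries. The 19 epithelial and stromal markers summed to 25.5 and 11.5 against 45.2 and 38.5, and mitochondrially encoded messenger RNAs to 45.0 and 22.5 against 92.2 and 78.9.

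Genes of cell division fell. Of 45 DNA replication and S phase genes 28 fell (35 adjusted over the list alone; median -0.71, adjusted p = 1.32e-21; adjusted p = 0.12 with an estimated correlation), and all 45 had a log2 change below 0. The replicative helicase subunits MCM4 and MCM5 fell 2.02-fold and 2.08-fold, the licensing factor CDC6 2.18-fold, and the sliding clamp PCNA 1.93-fold, from 932 ± 165 to 482 ± 89.6 CPM (n = 2). Of 43 replication-dependent histone genes 30 fell (36 adjusted over the list alone; median -0.83, adjusted p = 7.05e-26; adjusted p = 0.162 with an estimated correlation). They included H1-5 (1.92-fold), H3C10 (2.06-fold), H2BC8 (2.68-fold) and H4C4 (2.20-fold). Copies of these genes are nearly identical, so the share of each single copy is uncertain. Of 42 mitosis and G2/M genes 18 fell (32 adjusted over the list alone; median -0.59, adjusted p = 4.62e-14; adjusted p = 0.138 with an estimated correlation), among them CCNA2 (2.28-fold), CDK1 (2.17-fold) and BUB1 (1.84-fold). Without DIMT1 input replicate 1 the adjusted p was 0.0889 for CDC6, 0.0554 for CDK1 and 0.0576 for BUB1. Without DIMT1 input replicate 2 it was 0.0662 for MCM5, 0.0714 for CDK1 and 0.11 for BUB1.

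A further 10 lists were lower by smaller amounts. Cytosolic chaperones had a median of -0.35 (9 of 25 fell, 15 adjusted over the list alone, adjusted p = 4.12e-06), with TCP1, a subunit of the folding chamber for actin and tubulin, down 1.91-fold. Cholesterol biosynthesis had a median of -0.39 (7 of 25 fell, 9 over the list alone, adjusted p = 3.53e-05), with HMGCS1 at -1.04. Mitochondrial ribosomal proteins had a median of -0.36 (5 of 78 fell, 0 over the list alone, adjusted p = 1.9e-05). The spliceosome list stood at -0.30 (10 of 40 fell, 15 over the list alone, adjusted p = 8.6e-06). For these 4 lists the adjusted p was 0.12 with an estimated correlation. Ribosome assembly factors were lower for both subunits. The median of large subunit biogenesis factors was -0.28 (7 of 52 fell, 9 over the list alone, adjusted p = 9.3e-06), with BRIX1 at -0.86 and NOP16 at -0.96. The median of small subunit biogenesis factors, the class to which DIMT1 belongs, was -0.19 (7 of 60 fell, 7 over the list alone, adjusted p = 0.000599), with UTP20 at -0.77 and HEATR1 at -0.64. Proteasome genes had a median of -0.21 (6 of 37 fell, 6 over the list alone, adjusted p = 0.00021), with PSMA3 at -0.70. NOP16 shares 12.8% of its counted length with ARL10. With an estimated correlation these 3 lists also had an adjusted p = 0.12. MYC and core proliferation targets stood at -0.32 (12 of 35 fell, 16 over the list alone, adjusted p = 1.42e-05; adjusted p = 0.129 with an estimated correlation), with the nucleolar protein NPM1 at -0.75. RNA polymerase I and III subunits and factors stood at -0.27 (4 of 37 fell, 4 over the list alone, adjusted p = 0.00131; adjusted p = 0.17 with an estimated correlation). Nuclear-encoded oxidative phosphorylation stood at -0.14 (2 of 76 fell, 2 over the list alone, adjusted p = 0.0111; adjusted p = 0.205 with an estimated correlation), and without Rosa input replicate 2 its adjusted p was 0.0507. Without DIMT1 input replicate 1 the adjusted p was 0.123 for BRIX1, 0.179 for NOP16, 0.0737 for UTP20, 0.105 for HEATR1, 0.129 for PSMA3, 0.0549 for NPM1 and 0.0793 for HMGCS1. Without DIMT1 input replicate 2 it was 0.0778 for BRIX1, 0.111 for UTP20, 0.12 for HEATR1, 0.076 for PSMA3 and 0.157 for NPM1.

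The other 12 lists tested in input RNA were not called, with medians from -0.16 to 0.31 and adjusted p from 0.0571 to 0.776. They were the proteins of the small and of the large ribosomal subunit, translation initiation factors, translation elongation and termination factors, cytosolic aminoacyl-tRNA synthetases, RNA modification enzymes, interferon-stimulated genes, the unfolded protein response, integrated stress response targets, apoptosis regulators, glycolysis and the KMT2A fusion program. No list was called in input RNA with an estimated correlation. By fry, which asks whether the genes of a list move one way and does not compare them with other genes, 18 lists were called. Of these, 15 were also called by camera. The lists called by camera alone were histones (adjusted p = 0.0507 by fry) and oxidative phosphorylation (adjusted p = 0.0612 by fry).

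**Figure D3:**
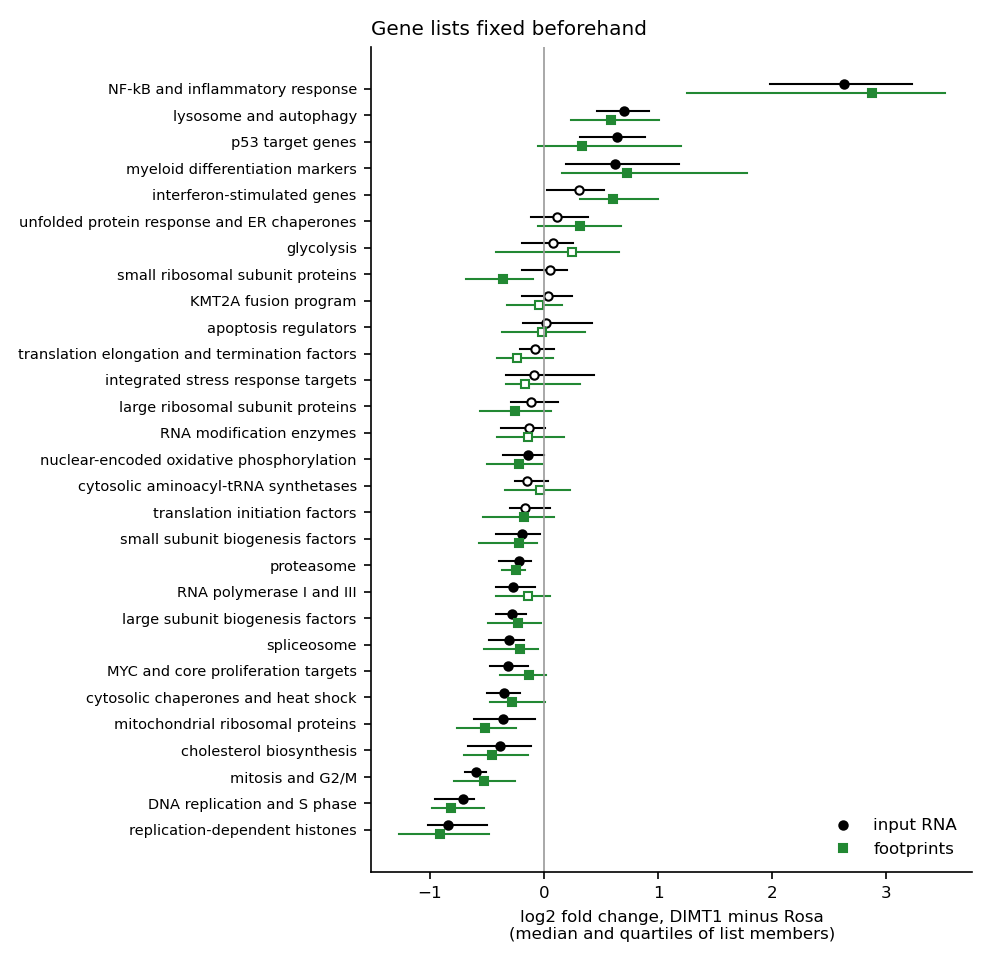
Median log2 fold change, DIMT1 minus Rosa (x axis), of each gene list with at least 5 measured members, in input RNA (circles) and in footprints (squares), with lines from the lower to the upper quartile of members. Filled symbols have an adjusted p under 0.05 by camera with a preset correlation and open symbols do not; the NF-kB and inflammatory response list stands highest in both assays, at 2.63 and 2.87, and the histone list lowest, at -0.83 and -0.90.

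The second comparison asked which messenger RNAs changed in ribosome footprints. Genes of inflammation were again among the largest increases, and 8 of the 9 genes that fell were histone genes. C3 rose 73.1-fold, from 5.42 ± 1.06 to 394 ± 43.3 CPM (n = 2; adjusted p = 8.81e-06), CXCL8 rose 23.7-fold to 958 ± 205 and IL4I1 rose 109-fold. In all, 65 of 7730 genes changed at an adjusted p under 0.05 in edgeR, 56 higher and 9 lower, each at least 2-fold. The unadjusted test gave 834 genes against 386 by chance. The count was 34 without Rosa footprint replicate 1, 39 without Rosa footprint replicate 2, 358 without DIMT1 footprint replicate 1 and 532 without the library labelled DIMT1 replicate 2. On counts simulated at these depths the test recovered 63% of 4-fold and 9% of 2-fold changes over 7730 genes, so smaller changes were mostly below detection.

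Among the 10 largest footprint increases, HLA-DRA rose 41.1-fold. The gelatinase MMP9 had 0 Rosa counts and 32 DIMT1 counts, at least 29.2-fold higher against a floor of 3 counts over the group. UMOD, which encodes the kidney protein uromodulin (ENSG00000169344, chromosome 16, 20333317 to 20350737), had 0 and 61 counts, at least 55.6-fold higher. The laminin gene LAMB2 (ENSG00000172037, chromosome 3, 49121229 to 49132867) had 1 and 54 counts, a ratio of 148 (25.4 to 5940). No input library held a count for UMOD or LAMB2. IL1B had a count ratio of 104 (17.6 to 4210), the chemokine CCL3 93.0 (15.6 to 3780), SGK1 66.6 (21.9 to 330) and the chemokine CCL4L2 50.6 (13.1 to 434). CCL3 and CCL4L2 have near-identical copies that the counting could have split, so their own values are uncertain. Without Rosa footprint replicate 1, CCL3 and IL1B lost their call. Without the library labelled DIMT1 replicate 2, only 3 of the 10 passed the low-count filter, and those 3 kept their call. HLA-DRA rose 26.5-fold without that library, and IL4I1 72.2-fold without Rosa footprint replicate 1. Of the 9 decreases, 8 were replication-dependent histone genes, namely H2AC13 (3.99-fold), H2BC17 (3.95-fold, from 262 ± 6.07 to 66.2 ± 0.318 CPM, n = 2), H4C4 (3.41-fold), H2BC4 (3.37-fold), H3C4 (3.07-fold), H2BC8 (2.76-fold), H4C8 (2.71-fold) and H2BC14 (2.49-fold). H3C4 shares 26.0% of its counted length with another gene, and single histone copies are uncertain. The ninth, the mitochondrial assembly factor TMEM70, fell 4.62-fold. Without Rosa footprint replicate 2, 7 of the 9 lost their call, as did 4 without Rosa footprint replicate 1. H2AC13 was 2.63-fold lower without Rosa footprint replicate 2, and H2AC13 and H2BC4 were 6.61-fold and 5.92-fold lower without the library labelled DIMT1 replicate 2.

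By list, footprints of 12 of the 21 measured NF-kB and inflammatory genes rose (18 adjusted over the list alone; median 2.87, adjusted p = 3.49e-47; adjusted p = 0.164 with an estimated correlation). They included NFKBIA (6.29-fold), TNF, the tumor necrosis factor (5.13-fold), and NFKB2 (7.44-fold). Footprints of 8 of 43 histone genes fell (25 adjusted over the list alone; median -0.90, adjusted p = 9.12e-21; adjusted p = 0.164 with an estimated correlation). Summed over the 55 genes of the list, histone footprints were 50770 and 61580 CPM in the Rosa libraries. They were 52920 in DIMT1 replicate 1 and 28730 in the library labelled DIMT1 replicate 2. The sum was thus lower only in the latter. In the DNA replication list none of 44 members passed over all genes and 14 fell when adjusted over the list alone (median -0.81, adjusted p = 6.52e-14; adjusted p = 0.164 with an estimated correlation). In the lysosome and autophagy list 4 of 30 rose (7 over the list alone; median 0.59, adjusted p = 6.72e-09; adjusted p = 0.383 with an estimated correlation), namely PSAP (5.45-fold), SQSTM1 (3.54-fold), LAMP1 (3.06-fold) and CTSH (10.1-fold). Its median was 0.39 without Rosa footprint replicate 1 and 0.33 without the library labelled DIMT1 replicate 2, and CTSH rose 6.19-fold without DIMT1 footprint replicate 1 and 16.3-fold without the library labelled DIMT1 replicate 2. Among the 28 myeloid markers CYBB (8.36-fold) and TYROBP (3.39-fold) rose (10 members over the list alone; median 0.73, adjusted p = 1.64e-09; adjusted p = 0.18 with an estimated correlation). Of 26 p53 targets, CD82 (3.84-fold), CDKN1A, which encodes the cell cycle inhibitor p21 (2.91-fold), and BTG2 (count ratio 26.5, 8.2 to 136) rose (7 over the list alone; median 0.34, adjusted p = 1.32e-05; adjusted p = 0.164 with an estimated correlation). That median was 0.51 without Rosa footprint replicate 2, 0.22 without DIMT1 footprint replicate 1 and 0.67 without the library labelled DIMT1 replicate 2. Without Rosa footprint replicate 1 the adjusted p was 0.22 for CD82, 0.201 for BTG2, 0.548 for CDKN1A, 0.425 for TYROBP, 0.145 for SQSTM1 and 0.237 for LAMP1. Without Rosa footprint replicate 2 it was 0.0521 for BTG2, 0.0906 for CDKN1A, 0.0561 for SQSTM1 and 0.226 for LAMP1. Alongside these increases, the lymphoid markers summed to 109 and 102 footprint CPM in the Rosa libraries, 736.4 in DIMT1 replicate 1 and 239 in the library labelled DIMT1 replicate 2. Of the 149 lymphoid counts in replicate 1, 103 were from NKG7, a granule protein of cytotoxic lymphocytes. The epithelial and stromal markers summed to 33.1 and 39.5 against 138.4 and 87.9.

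In the full set, footprints of 7 other lists were lower by camera with no member past the threshold over all genes. The same 7 lists were lower in every fit that left out 1 footprint library. They were mitochondrial ribosomal proteins (median -0.52; adjusted p = 0.164 with an estimated correlation), mitosis and G2/M (-0.52; adjusted p = 0.383 with an estimated correlation), cholesterol biosynthesis (-0.46, 1 member adjusted over the list alone), small subunit biogenesis factors (-0.22), the proteasome (-0.24), the spliceosome (-0.21) and large subunit biogenesis factors (-0.22). The last 5 also had an adjusted p = 0.164 with an estimated correlation. The median of small subunit biogenesis factors was -0.36 without Rosa footprint replicate 2 and -0.35 without the library labelled DIMT1 replicate 2. In the full set 9 of the 60 members of that list were above 0 and 51 below. Among the former, EMG1 stood at 3.22 ± 1.01 (SE, adjusted p = 0.326 in edgeR). EMG1 stood at 3.08 without Rosa footprint replicate 1 and at 4.15 without the library labelled DIMT1 replicate 2. The other 8 called lists each lost the call when 1 library was left out. Without the library labelled DIMT1 replicate 2 the adjusted p was 0.0679 for small ribosomal subunit proteins (median -0.36 in the full set), 0.144 for oxidative phosphorylation (-0.22) and 0.157 for interferon-stimulated genes (0.60). Without that library it was also 0.684 for large ribosomal subunit proteins (-0.25, and -0.14 without it), 0.236 for the unfolded protein response (0.32) and 0.578 for MYC targets (-0.13). Without DIMT1 footprint replicate 1 it was 0.438 for cytosolic chaperones (-0.27, and -0.14 without it) and 0.338 for translation initiation factors (-0.17, and -0.09 without it), and the median of MYC targets was -0.28. Without the library labelled DIMT1 replicate 2 the median of initiation factors was -0.41. Without Rosa footprint replicate 1 it was 0.15, 0.2, 0.114 and 0.0587 for chaperones, initiation factors, the unfolded protein response and MYC targets, and the median of chaperones was -0.13. Without Rosa footprint replicate 2 it was 0.118 for large ribosomal subunit proteins (median -0.16) and 0.0776 for MYC targets. With an estimated correlation the 8 lists had an adjusted p from 0.164 to 0.478. The remaining 8 lists were not called in footprints, with medians from -0.23 to 0.25 and adjusted p from 0.0658 to 0.82. Those were RNA polymerase I and III, translation elongation and termination factors, aminoacyl-tRNA synthetases, RNA modification enzymes, integrated stress response targets, apoptosis regulators, glycolysis and the KMT2A fusion program. No list was called in footprints with an estimated correlation, and 6 were called by fry, 5 of them also by camera. Those 5 were NF-kB, DNA replication, p53 targets, cholesterol biosynthesis and the spliceosome. By fry the adjusted p was 0.0885 for histones, 0.137 for lysosome and autophagy and 0.0918 for myeloid markers.

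Input RNA and footprint changes went together. Across 7640 genes tested in both assays, the log2 fold changes correlated at 0.608 (Pearson) and 0.48 (Spearman). These are values across genes, which are not independent replicates. Per the protocols both assays used parts of each lysate, so a difference between lysates could appear in both. Of the genes tested in both, 49 rose in both assays and 9 fell in both, where independent lists would share 3.25 and 0.534. None changed in opposite directions. Of 940 genes changed in input RNA, 864 (91.9%) had a footprint change of the same sign, against 63.1% of the genes not called in input RNA.

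**Figure D4:**
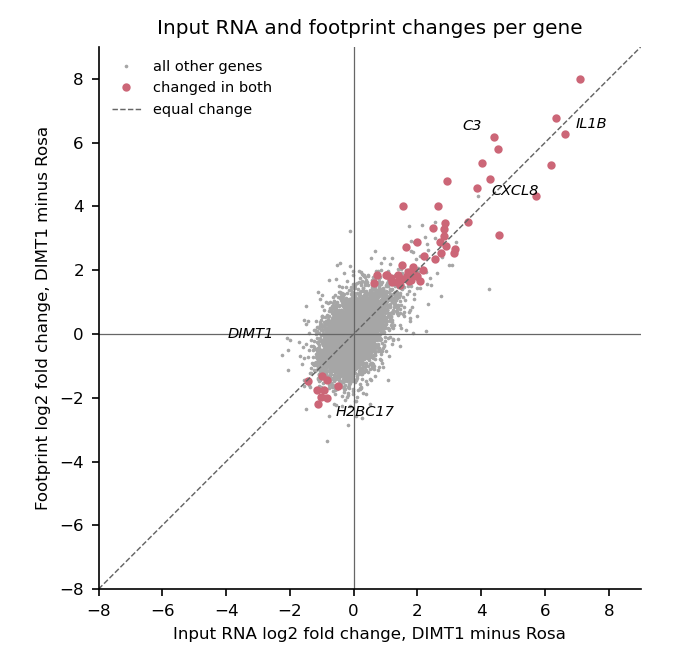
Log2 fold change, DIMT1 minus Rosa, in input RNA (x axis) and in footprints (y axis) for 7640 genes, 1 point per gene. Larger red points are genes with an adjusted p under 0.05 in both assays, 49 higher and 9 lower, and the dashed line marks equal change.

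The third comparison asked whether any messenger RNA changed in translational efficiency, the ratio of footprints to input RNA, tested as an interaction in 1 model over the 8 libraries. None of 9471 genes passed an adjusted p under 0.05 in edgeR, where the smallest was 0.951. DESeq2 and limma-voom also called 0. The unadjusted test gave 486 genes against 474 by chance. The count was 2 without DIMT1 footprint replicate 1 and 39 without the library labelled DIMT1 replicate 2. On simulated counts this test recovered 48% of 4-fold and 1% of 2-fold changes over 9471 genes, so only large changes were detectable. Libraries were scaled to each other, so a change in efficiency shared by most genes would be removed and could not be seen. The genes of smallest p, none of which passed, were VILL (log2 change 2.54 ± 0.59 SE), LSM7 (1.62 ± 0.35) and DCAF8 (1.51 ± 0.34) on the higher side, and ASB8 (-2.68 ± 0.62), SERP1 (-1.52 ± 0.40) and the ribosomal stalk protein RPLP1 (-1.27 ± 0.34) on the lower side. DCAF8 shares 11.2% of its counted length with another gene. DIMT1 stood at 1.54 ± 0.64 (adjusted p = 0.951), a value that rests on the library labelled DIMT1 replicate 2, without which it was -2.16 (adjusted p = 0.376). DCAF8 stood at 1.69 without that library (adjusted p = 0.0231).

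Of 29 lists, 1 was called for translational efficiency. Proteins of the small ribosomal subunit were lower relative to their input RNA, with a median log2 change of -0.48 and 26 of 33 members below 0 (adjusted p = 0.00173; adjusted p = 0.866 with an estimated correlation). None of the 33 passed the test for single genes, over all genes or adjusted over the list alone. RPS6 stood at -0.88 ± 0.28 (SE), RPS10 at -1.23 ± 0.47, RPS15 at -1.07 ± 0.42 and RPS29 at -0.85 ± 0.32. Members spread widely, from RPS3A at -2.23 to RPS26 at 3.16. The mean of the list was -0.30, and 7 members were above 0. RPS10 shares 56.9% of its counted length with the readthrough gene RPS10-NUDT3. Ribosomal protein genes have many processed pseudogenes, so reads of single members are uncertain. Without Rosa input replicate 1 the list's median was -0.38 and its adjusted p 0.244. Without the library labelled DIMT1 replicate 2 its median was -0.72, where the median of all genes was -0.235, and RPS6 stood at -1.20 (adjusted p = 0.0481). Large ribosomal subunit proteins had a median of -0.27 (adjusted p = 0.125). The NF-kB and inflammatory response list, with the largest changes in both assays, had a median of 0.05 in translational efficiency, and 13 of its 26 members were higher and 13 lower (adjusted p = 0.694). The 28 lists not called had medians from -0.27 to 0.31 and adjusted p from 0.125 to 0.964.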

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

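The crossed block and the thinning to equal depth were chosen after seeing the data, and the other alternatives before. Where 1 library was left out, the lone library of its group was assumed to vary like the other groups. No result named in the text reversed its sign past the threshold. The 1060 genes changed in input RNA became 432 with DESeq2 (426 of them shared), 288 in the fit over all 8 libraries, and 200 to 1699 when 1 library was left out. The 65 genes changed in footprints became 156 with limma-voom, 186 with no low-count filter, 18 with the stricter count filter (of 3445 genes tested), 106 at an adjusted p under 0.1, 10 after thinning to equal depth, 305 in the fit over all 8 libraries, and 34 to 532 when 1 library was left out. With no low-count filter 2 genes passed for translational efficiency in place of 0, and 0 to 39 passed when 1 library was left out. Without the library labelled DIMT1 replicate 2 the median change in translational efficiency of all genes was -0.235, so 18 higher and 21 lower calls there are not centred on 0. With an estimated correlation 0 lists were called in input RNA, footprints and translational efficiency, against 17, 21 and 1. Fry called 6 in footprints and 0 in translational efficiency. After thinning to equal depth 17 footprint lists were called. Small ribosomal subunit proteins, translation initiation factors, the unfolded protein response and MYC targets were no longer called there. For translational efficiency 2 lists were called after thinning to equal depth, and 0 to 5 when 1 library was left out. Across genes with an average log2 CPM of at least 5, the correlation of input RNA and footprint changes was 0.661. Thinning and the stricter filter left fewer counts or genes to test, and for the other changes the cause was not tested.

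Per the protocols, input RNA and footprints were parts of each lysate. The labels do not say what the replicate numbers mark or which libraries shared a lysate, so no pairing was assumed. Deviations of same-numbered libraries correlated at -0.111 between the input groups, -0.188 between the footprint groups, 0.168 between Rosa input and Rosa footprints, and 0.0164 between DIMT1 input and DIMT1 footprints. With the replicate block, 1096 genes changed in input RNA, 59 in footprints and 0 in translational efficiency, and 17, 19 and 1 lists were called. The unfolded protein response and MYC target lists were the 2 footprint lists no longer called. Pairing input and footprint libraries by treatment also gave 0 genes for translational efficiency, and lists were not tested in that fit. A crossed block gave 1667, 340 and 0 genes.

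Over all alternatives, values for named genes stayed on the same side of the threshold in 1797 cases for input RNA, 1784 for footprints and 2471 for translational efficiency. The call was lost in 287, 57 and 0 cases and gained in 61, 149 and 10. No gene was called for translational efficiency in the main fit, so no call could be lost there. Uncalled values counted as the same side even where their sign differed. Lists called kept the call in 133, 132 and 10 cases and lost it in 20, 57 and 3. Depth limits which footprints can be tested: at the depth of DIMT1 footprint replicate 1 (202332 counts) 4297 genes were tested, against 7730. Leaving out DIMT1 footprint replicate 1 or the library labelled DIMT1 replicate 2 raised the count to 358 or 532, and these libraries correlated at 0.911.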

Other observations

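Tests of library depth, of a mislabelled control library, of counting error and of the shallowest footprint library were chosen after the results they bear on were seen, and the tests of other lineages, coding length and pseudogenes before.

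Some genes of lists that were not called changed in input RNA. Among 30 integrated stress response targets 6 rose and 2 fell (6 and 3 adjusted over the list alone), with PPP1R15A, a phosphatase subunit that restores translation after stress, up 3.35-fold and the transcription factor ATF3 up 4.27-fold (11.5-fold without Rosa input replicate 1, and 2.55-fold with adjusted p = 0.0571 without Rosa input replicate 2). The adjusted p of ATF3 was 0.292 without DIMT1 input replicate 1 and 0.156 without replicate 2. The list's median was -0.09 and its mean 0.14, so these differ in sign (adjusted p = 0.715). Among 27 apoptosis regulators 4 rose and 2 fell (4 and 3 over the list alone), and BCL2A1, an anti-apoptotic member of the BCL2 family, rose 11.4-fold, from 6 to 39 summed counts (adjusted p = 0.0707 without DIMT1 input replicate 2). Large ribosomal subunit proteins went both ways, with 3 of 46 up and 3 down (4 and 3 over the list alone). RPLP2 rose by 0.91 and RPL28 by 0.81 on the log2 scale, and RPL38 and RPL14 stood at -0.45 and -0.55. The adjusted p of RPL38 was 0.202 and 0.346, and of RPL14 0.133 and 0.486, without DIMT1 input replicate 1 and 2. RPL14 stood at -0.36 without Rosa input replicate 2 (adjusted p = 0.103). METTL5, which methylates an adenosine in the same ribosomal RNA as DIMT1 and shares 0.4% of its counted length with SSB, fell (log2 change -1.06, adjusted p = 0.0101 in edgeR). It stood at -0.61 without Rosa input replicate 2 (adjusted p = 0.0844), and its adjusted p was 0.205 and 0.16 without DIMT1 input replicate 1 and 2. In the KMT2A fusion program 1 of 19 members rose, ZEB2 (0.57; adjusted p = 0.225 and 0.125 without DIMT1 input replicate 1 and 2), and the receptor kinase FLT3 stood at 0.36 (adjusted p = 0.0828, and 0.0169 without Rosa input replicate 1).

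Mitochondrially encoded messenger RNAs were almost missing from all 8 libraries, at 45.0 and 22.5 CPM in the Rosa and 92.2 and 78.9 in the DIMT1 input libraries. Summed counts were 83 and 45 in the Rosa and 98 and 82 in the DIMT1 input libraries. In both DIMT1 input libraries these messenger RNAs lay above both Rosa input libraries, but they were not tested as a list. Their footprints stood at 6.96 and 15.6 CPM in the Rosa libraries, 44.5 in DIMT1 replicate 1 and 12.4 in the library labelled DIMT1 replicate 2. Erythroid and megakaryocytic markers summed to 6.51 and 15.0 CPM in the Rosa and 8.47 and 8.66 in the DIMT1 input libraries, which overlap. UMOD and LAMB2 were the only genes with at least 20 footprint counts and 0 counts in the 4 input libraries. UMOD had 6 and 55 footprint counts in the DIMT1 libraries, the second in the library labelled DIMT1 replicate 2, and LAMB2 had 9 and 45.

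The NF-kB and inflammatory list rose in input RNA, where the DIMT1 libraries were shallower, but after thinning to equal depth 22 of 23 members still rose with a median of 2.72, which argues against library depth. Cells of another lineage stay open, because 61 erythroid, lymphoid, epithelial and stromal marker genes together were 1.86-fold higher in CPM (1.63 to 2.11; 492 counts in the DIMT1 and 485 in the Rosa input libraries), although 42 of them had 0 counts in all 4 libraries and 871 of 977 counts came from CD4, NKG7, ACTA2, IL7R and IGKC, and that interval spans the bound of 2 set in advance. An effect of DIMT1 loss on these genes is the biological explanation that the design names, and it was not tested apart from these.

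The control-level DIMT1 footprints in the library labelled DIMT1 replicate 2 were weighed against a wrong label and against counting error. Over 224 genes at least 2-fold higher in input RNA, that library lay 1.23 above the Rosa footprint libraries in the median on the log2 scale (replicate 1 lay 1.43 above, and the Rosa libraries differed by 0.17), which argues against a mislabelled control library. Its DIMT1 CPM were 1.20 times those of the Rosa footprint libraries (exact 95% interval 0.882 to 1.61), above the input RNA ratio of 0.302, which argues against counting error. Replicate 1 had a ratio of 0.0695 (0.00175 to 0.392), an interval that includes the input RNA ratio. A control-level DIMT1 value would need a mixture made mostly of Rosa cells, and the median of 1.23, near the 1.43 of replicate 1, argues against that. Both DIMT1 input libraries held few DIMT1 counts, 27 and 20, but the labels do not say which libraries shared a lysate. A mixture with cells other than the control, or a separate culture in which DIMT1 was expressed, stays open, and no biological explanation was tested.

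The lower footprint to input ratio of small ribosomal subunit proteins (median -0.48) was weighed against 3 technical explanations. Without the shallowest footprint library the median was -0.484 (adjusted p = 0.000193), which argues against that library as the cause. Of 10000 random lists matched on coding length and mean expression, 0 had a median as low (95% of them between -0.217 and 0.171). This argues against coding length as the source of the lower median. The lists were drawn gene by gene, so this spread does not cover lists whose genes vary together. Members with more annotated pseudogene copies had lower values, as predicted for reads shared with pseudogenes (Spearman rho -0.388 over 33 members, two-sided permutation p = 0.026). The median was -0.78 for the 16 members with most copies and -0.35 for the other 17. Among 46 large subunit proteins rho was 0.124 (permutation p = 0.409). A share of reads lost equally in both treatments would cancel in this measure. The correlation therefore cannot tell whether read assignment lowered the values. An effect of DIMT1 loss on translation of these proteins was not tested apart from read assignment. The call was lost by camera with an estimated correlation, where the adjusted p was 0.866.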
